A study of Arabidopsis thaliana with 12 samples.

How the data were processed

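Transcripts of whole Arabidopsis thaliana seedlings aged 8 days were measured by RNA sequencing in 12 libraries, 3 for each of 4 groups. The groups were formed from the sample titles, which name a genotype (KC or phod2) and a condition (P+ or P-). The condition was read as phosphate supply because the series title concerns phosphate, and the labels give no concentration. The labels do not spell out KC, nor do they state which gene is altered in phod2. Each library was made from 1.3 µg of total RNA extracted with a silica-column kit, per the labels' protocols. The series' design text states 3 biological replicates per genotype, so replicates were treated as separate biological samples. The labels name no sequencing batch or harvest time.

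The authors deposited 1 table with raw read counts per gene and FPKM values for every library, per the file headers. The aligner, the counting program, the annotation and the use of strand were not given in the sources used here. The genome build in the submitters' processing notes is mm10, a mouse assembly, whereas the gene identifiers and coordinates in the table are those of Arabidopsis. Of the 32833 genes in the table, 32548 matched a locus in the RefSeq annotation of Arabidopsis, and 99.95% of these had the same start and end there, so coordinates are given as deposited. The deposited FPKM values were recomputed from the counts, the exonic lengths and the library totals, and 100% lay within 0.006 of the recomputed value. The 3 KC P+ columns are headed WT in the deposited table, while the sample labels call these samples KC. A symbol stood beside 13415 genes, and 23 symbols had been turned into spreadsheet dates and were not used as names.

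Total counts ranged from 16821084 to 23327960 per library, and 23216 to 24013 genes had at least 1 count. A group without any count allowed a level of up to 0.0463 CPM in KC P+, 0.056 in KC P-, 0.0483 in phod2 P+ and 0.0537 in phod2 P-, each from a floor of 3 counts summed over the group. A fold against such a group is given as a lower bound, and a group with 1 to 3 counts is given as a ratio with its 95% counting interval. Intervals and floors cover counting error only. Plastid-encoded genes took 0.0325% to 0.0495% of the counts and mitochondrion-encoded genes 0.008% to 0.0345%. No pair of count columns was identical within a group. Reads from near-identical paralogs or overlapping genes may have been split or shared in the counting, and antisense partners cannot be told apart without strand, so values of members of such families (HSP17.6A with HSP17.6II, AOC1 with AOC2, VSP1 with VSP2, the PHT1, PDF1.2 and NAS families) are uncertain at the level of the single gene.

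The design assumed FPKM values with limma and foresaw edgeR in case raw counts were found. They were, and edgeR became the main tool. Counts were scaled with TMM factors, genes of low count were removed with filterByExpr (smallest count 10), and 20891 genes were tested with edgeR's quasi-likelihood test in 1 fit of 4 group means over all 12 libraries, with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p of at most 0.05 and a fold change of at least 2, the limits that the series' design text states. Contrasts were P- against P+ in each genotype, phod2 against KC in each condition, and the interaction (log2 change in phod2 minus that in KC). Log2 CPM used a prior count of 2, fitted changes edgeR's own. The common biological coefficient of variation was 8.47%. Normalized levels are TMM-scaled CPM (counts over the scaled library size) with the SD over 3 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

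Gene lists, named-gene rule, comparisons and alternatives were fixed before the data were examined. The 22 lists, with 373 entries that were all found in the table, covered phosphate transport, phosphate signalling, phosphatases and ribonucleases, membrane lipid remodelling, lipoate synthesis and lipoyl-dependent complexes, plastid fatty acid synthesis, nuclear photosynthesis genes, flavonoid and anthocyanin synthesis, iron homeostasis, sulfate starvation and assimilation, heat shock and protein folding, salicylate and defence, jasmonate, mitochondrial dysfunction, photorespiration, glucosinolate synthesis, starch and sugar, root hair markers, root tissue markers, seed storage and late embryogenesis markers, plastid-encoded genes and mitochondrion-encoded genes. Each was compared with all other genes by camera (limma) with a correlation of 0.01 between genes, adjusted over the 22 lists of a comparison, and again with an estimated correlation. Called members were counted with adjustment over all genes and adjusted over the list alone. Named genes were, per pairwise comparison, the 4 largest rises and falls among called genes with a symbol whose 3 values in a group all lay outside the range of the other group, up to 3 called members of each of the 6 lists with the most called members, and 6 genes named everywhere (LIP1P, SPX1, IPS1, PHT1;4, PAP17 and MGD3). For the interaction they were the 4 most positive and 4 most negative called genes and up to 3 called members of each list. Every named gene of the 4 pairwise comparisons had its 3 values in one group outside the range of the other, an arrangement that chance gives in 10% of genes and for which the largest rises and falls had been selected. Morning-phased and evening-phased clock genes (28) and 12 further genes were listed only after their values had been seen. Terms of the biological process ontology in the deposited table (744 terms of 10 to 500 genes) were tested by a one-sided hypergeometric test against the 11556 tested genes with a term, per direction.

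The test was tried on simulated data drawn from the real means and library sizes of 20891 genes, with 100 genes changed by each of 3-fold and 6-fold. For P- against P+ in KC, phod2 against KC in P- and the interaction, 100% of the changed genes of each size were recovered, with 1, 0 and 3 false calls. With nothing changed, P- against P+ in phod2 gave 0 false calls and phod2 against KC in P+ gave 1. The changed genes left out those of lowest level, the spread followed the dispersion trend rather than each gene, and no simulated library stood apart from its group. The recovery therefore does not cover genes of lowest level or contrasts with such a library. Of 200 random lists, 2% reached a camera p under 0.05 in the simulated P- against P+ in KC.

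Alternatives were limma on log2(FPKM + 1), with pseudocounts of 0.5 and 0.1, on TPM, on quantile-normalized values, without a variance trend and with library weights, DESeq2, median ratio scaling, no filter on low values, a mean of at least 5 FPKM, only the 6 libraries compared, the replicate number as a block, no fold threshold, and each library left out in turn. Fold changes in the FPKM and TPM fits are on the log2(value + pseudocount) scale, which understates changes of low genes. Chosen after seeing the data were removal of a gene-length trend per library, the separate list tests without phod2 P- replicate 2, and a filter at a mean of 10 normalized CPM.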

Results

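RNA of seedlings aged 8 days was sequenced for 2 genotypes, KC and phod2, in 2 conditions, P+ and P-, with 3 libraries in each of the 4 groups. Read counts summed to between 16821084 and 23327960 per library. The series title names LIP1p, a plastid-located lipoyl synthase, and phosphate homeostasis, so the comparisons ask how seedlings of each genotype differed between phosphate conditions and how phod2 differed from KC within each. Lipoyl synthases insert the sulfur atoms of the lipoyl cofactor carried by pyruvate dehydrogenase and related complexes. Whether phod2 carries a lesion in LIP1P is not stated in the labels. Columns of the KC P+ libraries are headed WT in the deposited table. If WT and KC were different lines, then P- against P+ in KC, phod2 against KC in P+ and the interaction would include that difference.

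LIP1P (AT5G08415, chromosome 5, 2710781 to 2713255 in the deposited coordinates) was detected in all 4 groups. Its normalized level was 33.4 ± 1.46 CPM in KC P+ (SD, n = 3 here and for all levels), 24.6 ± 0.663 in KC P-, 20.5 ± 0.997 in phod2 P+ and 13.8 ± 0.803 in phod2 P-. Compared with KC, the log2 difference of LIP1P in phod2 was -0.70 ± 0.068 (SE) in P+ and -0.83 ± 0.073 in P-, with 3 of 3 phod2 libraries below all KC libraries each time. These differences had adjusted p of 2.5e-06 and 1.6e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment but were smaller than 2-fold, so LIP1P was not called. Between conditions, LIP1P differed by -0.44 ± 0.067 in KC and by -0.57 ± 0.073 in phod2, also under 2-fold.

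The phosphate-starvation markers named in every comparison were lowest in KC P+ and highest in phod2 P-. SPX1 (AT5G20150, chromosome 5, 6802282 to 6803655), which encodes a phosphate-status sensor, had levels of 6.35 ± 0.476 in KC P+, 135 ± 6.57 in KC P-, 54.0 ± 2.08 in phod2 P+ and 501 ± 57.2 in phod2 P-. IPS1 (AT3G09922, chromosome 3, 3050989 to 3051530), a non-coding RNA that sequesters a microRNA, had levels of 0.464 ± 0.105, 11.3 ± 0.887, 4.37 ± 1.13 and 103 ± 24.5 in the same order. PAP17 (AT3G17790, chromosome 3, 6089381 to 6091231), a purple acid phosphatase gene, stood at 4.23 ± 0.525, 131 ± 4.73, 46.1 ± 1.95 and 379.7 ± 25.9. The phosphate transporter gene PHT1;4 (AT2G38940, chromosome 2, 16257157 to 16260253) stood at 8.95 ± 1.02, 64.4 ± 2.96, 24.3 ± 2.08 and 118 ± 1.68. For MGD3 (AT2G11810, chromosome 2, 4743162 to 4746813), a galactolipid synthase gene, the levels were 1.49 ± 0.174, 9.33 ± 0.745, 14.3 ± 1.11 and 50.2 ± 3.22, so that phod2 P+ lay above KC P- for this gene.

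**Figure D1:**
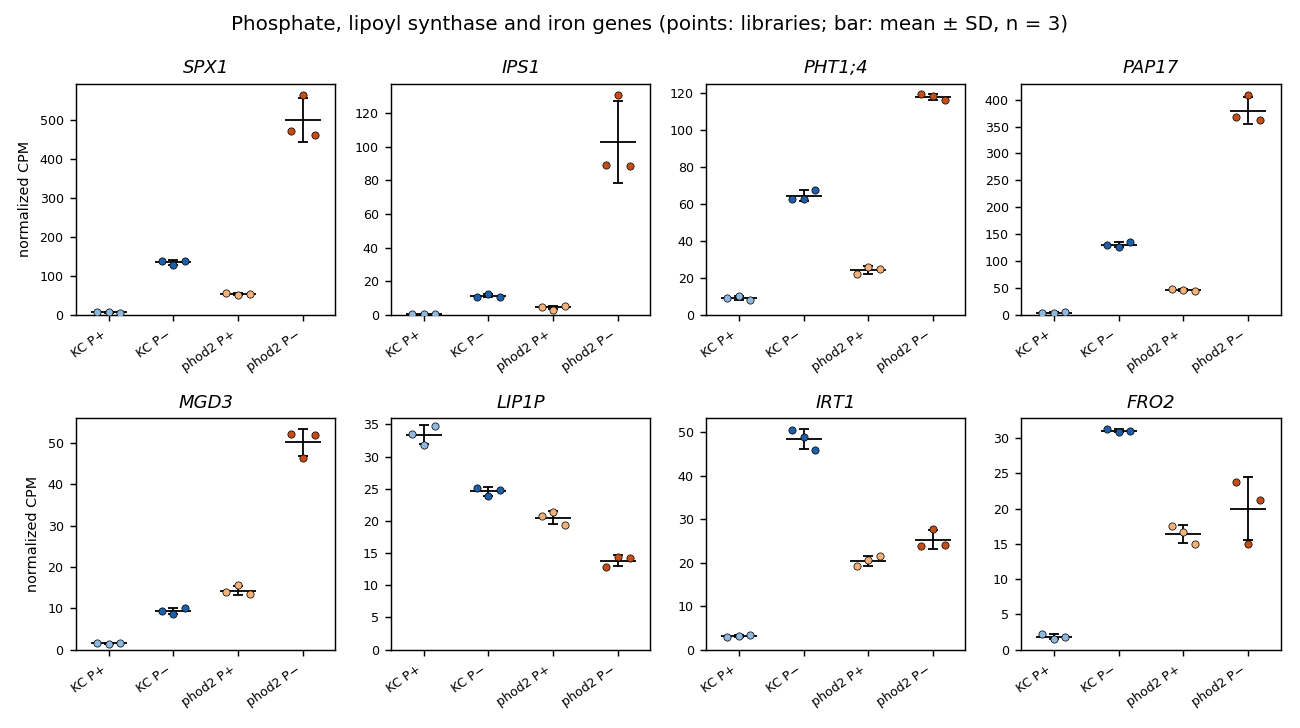
Normalized CPM (vertical axis) of SPX1, IPS1, PHT1;4, PAP17, MGD3, LIP1P, IRT1 and FRO2 in the 4 groups, with points for the libraries and bars for the mean ± SD of 3. SPX1 reached 501 in phod2 P- against 6.35 in KC P+, whereas IRT1 was highest in KC P- at 48.4.

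The first principal component took 72.3% of the variance and set the P+ libraries (-77.7 to -72.8) apart from the P- libraries (65.8 to 91.5). The second took 14.8% and set KC (-36.5 to -31.3) apart from phod2 (24.8 to 41.4). Replicate 2 of phod2 P- stood apart from the other 2 libraries of its group. Its counts differed from theirs with gene length, at a Spearman correlation of -0.69 across genes, which are not independent replicates. The tenth of genes with the shortest exons (at most 891 bases) had a median log2 difference of 0.46 there. The tenth with the longest (at least 3186 bases) had a median of -0.66.

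**Figure D2:**
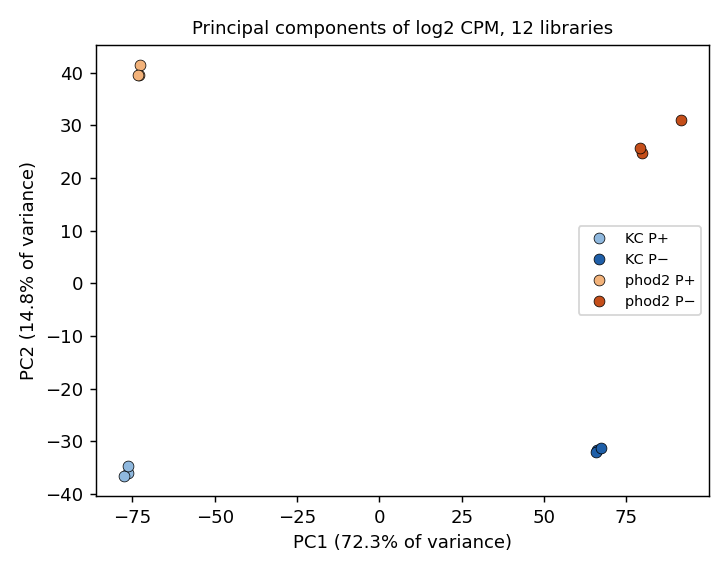
Scores of the 12 libraries on principal components 1 (72.3% of the variance, horizontal) and 2 (14.8%, vertical), with 1 point per library, coloured by group. The P+ and P- libraries separate along the first axis and the genotypes along the second, and phod2 P- replicate 2 lies farthest out at 91.5.

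**Figure D3:**
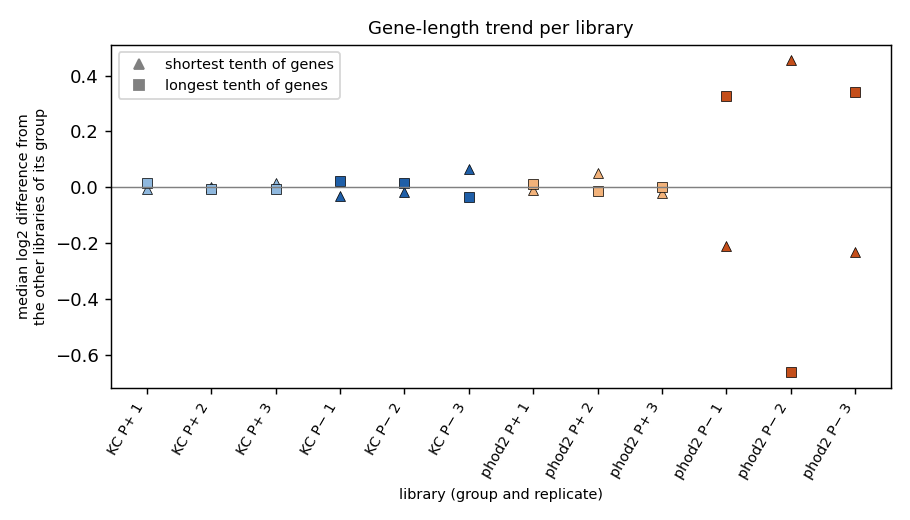
Median log2 difference of each library from the other libraries of its group (vertical axis) over the tenth of genes with the shortest exons (triangles) and the tenth with the longest (squares), for all 12 libraries (horizontal axis). Replicate 2 of phod2 P- stands at 0.46 and -0.66, and the 9 libraries of the other groups lie between -0.035 and 0.065.

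In KC, the phosphate, sulfate and flavonoid genes named here were higher in P- than in P+. Among phosphate genes, PS2, which encodes a pyrophosphatase, rose 94.5-fold (6.56 ± 0.14, log2 ± SE here and below), the vacuolar phosphate exporter gene VPE1 50.1-fold (5.65 ± 0.1), PECP1 42.1-fold, PAP17 30.7-fold (4.94 ± 0.093), IPS1 24.1-fold (4.59 ± 0.304), SPX1 21.2-fold (4.41 ± 0.098), PHT1;4 7.22-fold (2.85 ± 0.09) and MGD3 6.21-fold (2.63 ± 0.13). The plastid phosphate transporter gene PHT2;1 rose 3.6-fold. LDOX rose from 4.75 ± 0.372 to 137 ± 3.04 CPM, DFR from 10.7 ± 0.986 to 173 ± 0.6 and UF3GT from 1.76 ± 0.325 to 39.4 ± 1.02, all of them late anthocyanin genes. APR1, which encodes a sulfate-assimilating reductase, rose from 21.4 ± 1.9 to 312 ± 8.62. SDI1 rose by a log2 of 4.19 ± 0.096 and SDI2 10.2-fold.

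Of 20891 genes tested, 4292 were called between P- and P+ in KC, 2286 higher and 2006 lower in P-. The split turned to 1347 higher and 1403 lower in limma on log2(FPKM + 1), and to 1470 and 1687 on TPM. Each called named gene was higher or lower in 3 of 3 P- libraries than in all P+ libraries, with adjusted p from 2.44e-17 to 1.1e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest rises by fitted log2, which depends on the prior count for groups of 0 to 3 counts here and in the other comparisons, were of MIP1A, which had 0 counts in P+ and was at least 107-fold higher in P-, LNK3 (686-fold), CCA1 (461-fold) and SWEET15 (393-fold). The largest falls by the same measure were of CYP71B22 and PCR1, without counts in P- and at least 148-fold and 39.2-fold lower, DRMH1 (1200-fold) and COR27 (498-fold). The clock genes JMJ30 (-7.30 ± 0.136) and COR28 (-7.21 ± 0.188) fell by more than the bound of PCR1.

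Phosphatases and ribonucleases rose in 11 of 13 members and fell in 0 (median log2 2.43, or 2.40 with PAP25 at its bound, camera adjusted p = 1.05e-06). The same numbers passed when adjusted over the list alone, as did those of every list below unless stated. Phosphate transport rose in 10 of 16 members and fell in 0 (median 1.44, camera adjusted p = 8.93e-05). Membrane lipid remodelling rose in 9 of 18 members and fell in 1 (median 1.05, camera adjusted p = 0.00134, and adjusted p = 0.148 with an estimated correlation). Flavonoid and anthocyanin genes rose in 20 of 23 members (median 3.35, camera adjusted p = 6.55e-12), sulfate genes in 14 of 17 (2.55, 7.74e-08), mitochondrial dysfunction genes in 7 of 9 (2.03, 2.51e-05), glucosinolate genes in 9 of 19 (0.95, 2.78e-06) and root hair markers in 5 of 11 (0.85, 0.00189), with 0 falls in each. Heat shock genes rose in 11 of 15 members and fell in 1 (median 2.52, or 2.44 with HSP17.6II, HSP21 and HSP23.6 at their bounds, camera adjusted p = 0.000622, and adjusted p = 0.0811 with an estimated correlation). Among them CLPB3 was 7.93-fold higher, HSP70 6.03-fold and HSP90.1 5.59-fold. Iron genes rose in 11 of 26 members and fell in 3 (median 0.33, camera adjusted p = 0.0461, and adjusted p = 0.0898 with an estimated correlation). The nicotianamine synthase genes NAS2 and NAS1 were 22.0-fold and 4.85-fold higher and the iron transporter gene IRT1 higher by a log2 of 3.98 ± 0.098. Nuclear photosynthesis genes rose in 7 of 38 members (median 0.15, camera adjusted p = 0.0163, and adjusted p = 0.678 with an estimated correlation) and mitochondrion-encoded genes in 4 of 14 (0.85, 0.0461, and adjusted p = 0.326 with an estimated correlation). After quantile normalization and with the length trend removed, the camera adjusted p was 0.434 and 0.11 for photosynthesis, 0.0995 and 0.109 for iron and 0.146 and 0.17 for mitochondrion-encoded genes. On log2(FPKM + 0.1) it was 0.0583 for the last of these. Under the replicate block it was 0.0529 for iron and for mitochondrion-encoded genes. Iron missed the threshold without KC P+ replicate 2 (0.0622), phod2 P+ replicates 2 (0.0524) or 3 (0.0521) or phod2 P- replicates 1 (0.0544), 2 (0.113) or 3 (0.0523). Mitochondrion-encoded genes missed it without KC P+ replicates 1 (0.0597) or 2 (0.0661), KC P- replicates 1 (0.0596) or 2 (0.0532) or phod2 P- replicates 1 (0.0544), 2 (0.101) or 3 (0.0549).

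The remaining lists did not pass the camera test in KC. They were phosphate signalling (6 higher and 2 lower of 19, adjusted p = 0.174), lipoate synthesis and lipoyl-dependent complexes (0 and 1 of 28, 0.366), plastid fatty acid synthesis (0 and 0 of 20, 0.29), photorespiration (2 and 0 of 14, 0.174), starch and sugar (5 and 2 of 9, 0.241), jasmonate (5 and 5 of 17, 0.569), root tissue markers (2 and 2 of 16, 0.569), and plastid-encoded genes (9 and 0 of 78, or 8 higher adjusted over the list alone, 0.0922). Salicylate and defence genes (2 higher and 3 lower of 19, camera adjusted p = 0.76) had a median of 0.03, a mean of -0.45 and a camera direction upward, and without phod2 P- replicate 2 a median of -0.075. Seed markers (2 and 2 of 9, 0.95) had a median of -0.20, a mean of -0.02 and a camera direction upward.

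Clock genes differed between the conditions in KC together with all of these groups. Of 15 morning-phased genes 14 rose (median log2 4.69), and of 13 evening-phased genes 11 fell and 1, GI, rose (median -4.10). These lists were made after the values had been seen. The labels give no harvest time, so in either genotype differences between P- and P+ could not be told apart from differences in time of day. CCA1, a core morning gene of the clock, stood at 0.325 ± 0.271 in P+ and 159 ± 4.29 in P-, and COR27, an evening gene, at 115 ± 2.16 and 0.222 ± 0.0428. Among biological process terms, response to karrikin held 40 higher genes of 99 (11.4 expected, one-sided hypergeometric adjusted p = 1.06e-10), response to high light intensity 23 of 55 (6.33 expected, adjusted p = 1.83e-06) and, among lower genes, circadian rhythm 21 of 91 (8.49 expected, adjusted p = 0.0137). In all, 52 terms passed for higher and 8 for lower genes. On the log2(FPKM + 1) scale limma called 2750 genes, which is over 1.5 times fewer.

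**Figure D4:**
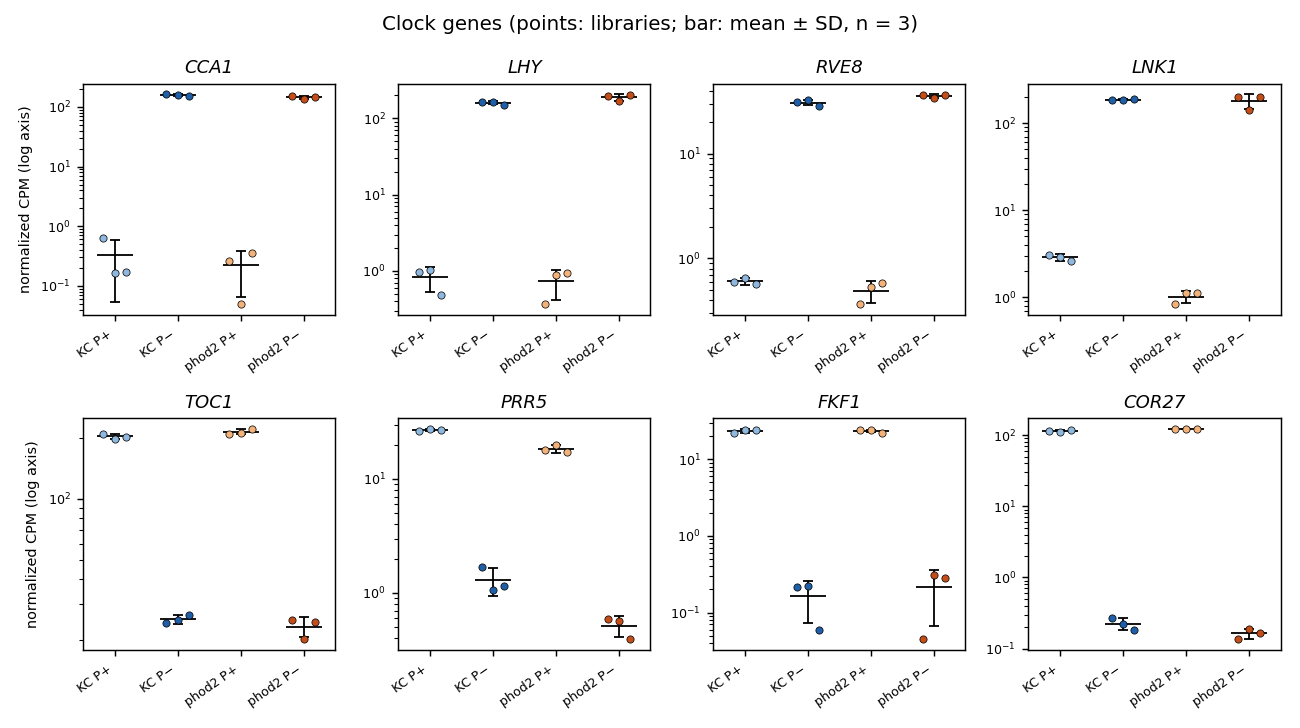
Normalized CPM (vertical log axis) of CCA1, LHY, RVE8, LNK1, TOC1, PRR5, FKF1 and COR27 in the 4 groups, with points for libraries and mean ± SD of 3. CCA1 lies near 0.325 and 0.223 in the P+ groups and near 159 and 144 in the P- groups, and COR27 goes the other way.

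In phod2, the phosphate genes named here also rose in P-. PECP1 was 43.3-fold higher in P- (5.44 ± 0.12), PS2 28.9-fold (4.86 ± 0.107), IPS1 23.3-fold (4.54 ± 0.185), VPE1 9.29-fold (3.22 ± 0.082), SPX1 9.27-fold (3.21 ± 0.086), PAP17 8.24-fold (3.04 ± 0.078), PHT1;4 4.84-fold (2.28 ± 0.083), MGD3 3.52-fold (1.82 ± 0.083) and PHT2;1 2.58-fold. LDOX rose from 7.93 ± 0.951 to 361 ± 13.8, DFR from 17.1 ± 0.897 to 466 ± 10.1 and UF3GT from 3.04 ± 0.255 to 121 ± 6.0. SDI1 rose 25.0-fold, APR1 14.1-fold and SDI2 9.54-fold, and the glucosinolate genes CYP79F1, FMOGS-OX1 and CYP83A1 rose 6.88-fold, 5.99-fold and 2.91-fold. In contrast to these, IRT1 (0.30 ± 0.08) and the ferric reductase gene FRO2 (0.30 ± 0.135) were not called in phod2.

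Between P- and P+ in phod2, 5102 genes were called, 2945 higher and 2157 lower. On the TPM scale the split was 1754 higher and 2190 lower, and the median log2 of all genes was -0.15 on that scale and 0.0086 in edgeR. Called named genes had all 3 P- libraries on one side of the P+ libraries, with adjusted p from 2.23e-17 to 8.32e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By fitted log2 the largest rises were of ATCSLA01, with 2 counts in P+ (ratio 1770, counting interval 490 to 14600), MIP1A and PAP5, with 0 counts in P+ and at least 163-fold and 83.6-fold higher, and CCA1 (622-fold). By fitted log2 the largest falls were of DRMH1 (2010-fold), COR27 (726-fold), and PCR1 and DREB1B, without counts in P- and at least 89.0-fold and 27.7-fold lower.

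Flavonoid genes rose in 21 of 23 members (median log2 4.57, camera adjusted p = 8.45e-14), phosphatases in 12 of 13 (3.10, 4.73e-07), phosphate transport in 13 of 16 (1.78, 1.89e-05), sulfate genes in 13 of 17 (2.94, 1.8e-07), mitochondrial dysfunction genes in 7 of 9 (1.73, 3.22e-05), root hair markers in 9 of 11 (1.58, 0.000185) and seed markers in 8 of 9 (2.43, 0.000921), with 0 falls in each list. The numbers adjusted over the list alone were the same here and below unless stated. Glucosinolate genes rose in 12 of 19 members and fell in 1 (median 1.26, camera adjusted p = 4.73e-07), and heat shock genes rose in 13 of 15 and fell in 1 (2.75, 1.38e-05), with HSP70 12.2-fold, CLPB3 8.13-fold and ROF2 4.48-fold higher. Membrane lipid remodelling rose in 12 of 18 members (median 1.74, camera adjusted p = 0.000533, and adjusted p = 0.122 with an estimated correlation), and nuclear photosynthesis genes in 6 of 38 (0.38, 0.00108, and adjusted p = 0.748 with an estimated correlation). Lists that did not pass were phosphate signalling (6 higher and 3 lower, camera adjusted p = 0.1), root tissue markers (4 and 0, 0.0721), mitochondrion-encoded genes (3 and 0, or 2 higher adjusted over the list alone, 0.0721), plastid-encoded genes (0 and 2, 0.391), starch and sugar (5 and 3, 0.413), jasmonate (6 and 4, 0.566), photorespiration (1 and 0, 0.628) and plastid fatty acid synthesis (0 and 0, 0.84). Lipoate genes (1 higher and 1 lower, camera adjusted p = 0.917) had a median of 0.02 and a mean of -0.02, iron genes (5 and 4, 0.917) a median of -0.003 and a mean of -0.06, each with a camera direction upward. Salicylate genes (1 and 2, or 2 and 2 adjusted over the list alone, 0.917) had a median of 0.05 and a mean of -0.10 with a direction downward. Without phod2 P- replicate 2, the library with the length trend, the photosynthesis median was 0.24, 0 glucosinolate and 4 plastid-encoded genes were lower and 3 salicylate genes were higher, and the medians of lipoate, iron and salicylate genes were 0.07, -0.12 and 0.20. After quantile normalization photosynthesis missed the camera threshold (adjusted p = 0.63). Phosphate signalling passed with the length trend removed (0.0431) and mitochondrion-encoded genes passed without phod2 P+ replicate 2 (0.04).

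Clock genes moved with these groups in phod2 as they did in KC, with 14 of 15 morning-phased genes higher (median log2 4.39) and 11 of 13 evening-phased genes lower with GI higher (-4.38). Response to karrikin held 43 higher genes of 99 (14.3 expected, one-sided hypergeometric adjusted p = 1.67e-09), glutathione metabolic process 25 of 42 (6.05 expected, adjusted p = 6.17e-09) and circadian rhythm 25 lower genes of 91 (9.25 expected, adjusted p = 0.00189), among 50 terms for higher and 7 for lower genes. The comparison includes the library with the length trend, and without it 4886 genes were called. Of the genes called in KC and in phod2, 3464 were shared. In both genotypes 1880 were higher, against 322 from independent lists, and 1567 were lower, against 207, while 17 went in opposite directions, against 519. Across genes, which are not independent replicates, the 2 sets of log2 changes had r = 0.893.

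In P+, the phosphate-starvation and iron-uptake genes named here were higher in phod2 than in KC, and the root genes lower. PAP17 was 10.8-fold higher (3.44 ± 0.092), VPE1 10.3-fold (3.36 ± 0.099), MGD3 9.51-fold (3.25 ± 0.122), IPS1 9.36-fold (3.23 ± 0.35), the phosphodiesterase gene GDPD1 9.05-fold (3.18 ± 0.094), SPX1 8.51-fold (3.09 ± 0.096), PHT1;4 2.73-fold (1.45 ± 0.091) and the sulfolipid synthesis gene SQD1 2.29-fold. FRO2 rose from 1.84 ± 0.393 in KC to 16.4 ± 1.34 in phod2, IRT1 from 3.08 ± 0.256 to 20.4 ± 1.2 and NAS2 from 2.90 ± 0.251 to 10.8 ± 0.151. The iron-responsive cytochrome P450 gene CYP82C4 rose from 0.369 ± 0.181 to 7.28 ± 0.212. EXPA7, an expansin gene of root hairs, fell from 7.98 ± 0.318 to 2.16 ± 0.434, CASP1 of the endodermal Casparian strip from 32.0 ± 2.48 to 8.0 ± 0.645, and PYK10, a root glucosidase gene, from 3831 ± 28.6 to 1611 ± 10.8.

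Of 20891 genes, 1545 were called between phod2 and KC in P+, 413 higher and 1132 lower in phod2. All 3 phod2 libraries lay on one side of the KC libraries for each called named gene, and adjusted p ran from 1.27e-11 to 5.08e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By fitted log2 the largest rises were of anac085, with 0 counts in KC and at least 16.3-fold higher, DTX3 (22.5-fold), CYP82C4 (19.3-fold) and NUDT24 (16.9-fold). By fitted log2 the largest falls were of CYP71A20, with 0 counts in phod2 and at least 24.6-fold lower, the marneral synthase gene MRN1 (91.2-fold), DTX20, with 1 count in phod2 (KC to phod2 ratio 101, counting interval 17.7 to 4010), and AGP30 (34.1-fold), which encodes an arabinogalactan protein.

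Root hair markers fell in 9 of 11 members and rose in 0 (median log2 -1.68, camera adjusted p = 4.65e-11), with PRX44 4.44-fold and RHD2 3.2-fold lower. Root tissue markers fell in 7 of 16 and rose in 1 (median -0.78, camera adjusted p = 8.07e-06), with the aquaporin gene TIP2;3 5.8-fold lower. Iron genes rose in 10 of 26 members and fell in 1 (median 0.70, camera adjusted p = 2.06e-05), and the root markers are expressed in the same organ as IRT1 and FRO2. Phosphatases rose in 4 of 13 members (5 adjusted over the list alone) and fell in 0 (median 0.79, or 0.66 with PAP25 at its bound, camera adjusted p = 0.000262), starch and sugar genes in 4 of 9 (0.95, 0.00121) and mitochondrial dysfunction genes in 3 of 9 (0.70, 0.00444). Membrane lipid remodelling rose in 6 of 18 members and fell in 1 (median 0.36, camera adjusted p = 8.07e-06, and adjusted p = 0.0575 with an estimated correlation). Plastid-encoded genes rose in 3 of 78 (2 adjusted over the list alone, median 0.38, camera adjusted p = 0.000573, and adjusted p = 0.185 with an estimated correlation), and seed markers in 2 of 9 (3 adjusted over the list alone, 0.69, 0.0277, and adjusted p = 0.123 with an estimated correlation). Without phod2 P- replicate 2, 6 of 80 plastid-encoded genes were higher. Seed markers missed the camera threshold on log2(FPKM + 0.1) (adjusted p = 0.149), after quantile normalization (0.102) and with the length trend removed (0.0508). Plastid-encoded genes missed it with the length trend removed (0.0508).

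Other lists did not pass in this comparison. Flavonoid genes had 2 higher members (3 adjusted over the list alone) and 4 lower (camera adjusted p = 0.796), with CHS, FLS1 and MYB12 2.7-fold, 2.49-fold and 2.76-fold lower. On log2(FPKM + 1), after quantile normalization and with library weights MYB12 was under 2-fold, at -0.86, -0.79 and -0.86. Phosphate transport had 2 higher and 3 lower members (camera adjusted p = 0.706), among them PHT1;1 at 2.13-fold lower. Phosphate signalling had 4 and 1 (0.239), with a median of -0.01, a mean of 0.52 and an upward camera direction. Sulfate genes (2 and 1, or 3 and 1 adjusted over the list alone, 0.483), heat shock genes (0 and 0, or 1 higher adjusted over the list alone, 0.706), salicylate (1 and 2, 0.0662), jasmonate (0 and 1, 0.657), photorespiration (0 and 0, 0.124), glucosinolate (0 and 0, 0.193), nuclear photosynthesis (0 and 0, 0.796), plastid fatty acid synthesis (0 and 0, 0.188) and mitochondrion-encoded genes (0 and 0, 0.788) did not pass either. Lipoate genes, LIP1P among them, had 0 called members of 28 (camera adjusted p = 0.362), a median of 0.005, a mean of -0.06 and a camera direction downward. Without phod2 P- replicate 2, 2 heat shock genes were higher, and the medians of phosphate signalling and lipoate genes were -0.036 and -0.02, and fatty acid synthesis (camera adjusted p = 0.0351) and photorespiration (0.0111) passed. Clock genes were called in 2 of 28 cases in edgeR, LNK1 (-1.47 ± 0.227) and GI (-1.002 ± 0.17). Among lower genes, hydrogen peroxide catabolism held 29 of 83 (4.46 expected, one-sided hypergeometric adjusted p = 7.38e-14) and suberin synthesis 8 of 15 (0.806 expected, adjusted p = 4.55e-05). Among higher genes cellular response to phosphate starvation held 8 of 62 (1.17 expected, adjusted p = 0.00493), of 25 and 8 terms past the threshold. On the log2(FPKM + 1) scale limma called 633 genes.

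Genes called for P- in KC and for phod2 in P+ overlapped in 629 cases, comparisons that share the 3 KC P+ libraries. Both were higher in 214 (45.2 from independent lists), both lower in 213 (109), and 202 went in opposite directions (164). Across genes the log2 changes had r = 0.192 and a covariance of 0.137, against 0.473 and 0.0222 in 20 simulations of unchanged groups with shared libraries. With 3 shared libraries the controls were too few to split, part of the excess may come from sharing them, and the same simulations gave at most 0 calls for P- in KC and 0 joint calls. They leave open how many joint calls sharing adds where genes differ.

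In P-, the phosphate, lipid-remodelling, anthocyanin and seed genes named here were higher in phod2 than in KC. IPS1 was 9.08-fold higher (3.18 ± 0.167), PECP1 7.19-fold (2.85 ± 0.099), MGD3 5.39-fold (2.43 ± 0.089), PS2 4.64-fold (2.22 ± 0.093), SPX1 3.71-fold (1.89 ± 0.081), MGD2 3.16-fold, PAP17 2.91-fold (1.54 ± 0.073) and SQD1 2.13-fold (log2 of 0.98 after quantile normalization), whereas PHT1;4 differed by 0.87 ± 0.078 and was not called. F3PH rose from 42.1 ± 0.873 in KC to 148 ± 7.78 in phod2, UF3GT from 39.4 ± 1.02 to 121 ± 6.0 and DFR from 173 ± 0.6 to 466 ± 10.1. The seed storage protein gene CRU1 rose from 0.635 ± 0.126 to 35.1 ± 1.62, PER1 from 0.786 to 11.6 and the oleosin gene OLEO2 from 0.684 to 6.64. AGP30 fell from 24.5 ± 0.33 to 0.437 ± 0.0929, a fall of 54.0-fold.

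Between phod2 and KC in P-, 979 genes were called, 466 higher and 513 lower. Called named genes had 3 of 3 phod2 libraries beyond all KC libraries, with adjusted p from 9.59e-11 to 0.000261 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Besides CRU1 (54.7-fold), the largest rises by fitted log2 were of M17, CRU3 and EIL4, each with 1 count in KC, at ratios of 314 (counting interval 56.0 to 12500), 98.7 (17.3 to 3940) and 96.8 (17.0 to 3860). Besides AGP30, the largest falls by fitted log2 were of CLE5, with 2 counts in phod2 (KC to phod2 ratio 77.2, interval 21 to 643), GRXC11, with 1 count (78.3, 13.6 to 3130), and LBD14, with 0 counts in phod2 and at least 7.29-fold lower. LBD14 was under 2-fold on log2(FPKM + 1) and without a variance trend (-0.67), with library weights (-0.67), on TPM (-0.98) and after quantile normalization (-0.58), scales that shrink changes of low genes. Without the library that showed the length trend 1025 genes were called.

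Flavonoid genes rose in 14 of 23 members (median log2 1.32, camera adjusted p = 4.35e-14), phosphatases in 10 of 13 (1.72, 1.09e-11), membrane lipid remodelling in 8 of 18 (0.86, 7.74e-12), seed markers in 8 of 9 (2.93, 1.29e-09), heat shock genes in 8 of 15 (1.06, 4.48e-07) and mitochondrial dysfunction genes in 3 of 9 (0.56, 1.39e-05), with 0 falls in each and the same numbers adjusted over the list alone, as for all lists here. Without the library that showed the length trend, the rises numbered 13, 11, 8, 8 and 8 in the first 5 of these lists. Among heat shock genes, HSP17.6A was 7.99-fold, HSP17.6II 7.12-fold and HSP15.7 2.66-fold higher. Jasmonate genes rose in 5 of 17 members and fell in 2 (median 0.63, camera adjusted p = 2.89e-05), with VSP2 3.58-fold, AOC1 2.94-fold and AOC2 2.39-fold higher. Root hair markers fell in 6 of 11 members (median -1.14, camera adjusted p = 5.22e-10), or in 5 without that library, and root tissue markers in 1 of 16 (-0.37, 2.89e-05). Glucosinolate genes passed with 0 members called in edgeR and a median of 0.48 (camera adjusted p = 2.99e-06). Sulfate genes rose in 5 of 17 and fell in 1 (median 0.33, camera adjusted p = 0.0417, and adjusted p = 0.11 with an estimated correlation). Phosphate signalling rose in 4 of 19 (median -0.03, mean 0.53, upward, camera adjusted p = 0.0417, and adjusted p = 0.0753 with an estimated correlation). Lipoate genes (median -0.13, camera adjusted p = 0.00913, and adjusted p = 0.0753 with an estimated correlation), plastid fatty acid synthesis (-0.13, 0.00662, and adjusted p = 0.0722 with an estimated correlation) and nuclear photosynthesis genes (0.15, 0.00954, and adjusted p = 0.661 with an estimated correlation) each had 0 called members in edgeR. The medians of photosynthesis and phosphate signalling were -0.004 and 0.057 without the library with the length trend. Photosynthesis missed the camera threshold without that library (adjusted p = 0.721, direction reversed), after quantile normalization (0.76, direction reversed) and with the length trend removed (0.155). Phosphate signalling missed it on log2(FPKM + 0.1) (0.0509) and without KC P- replicate 3 (0.0536) or phod2 P- replicates 1 (0.0642) or 3 (0.0726). Sulfate genes missed it without phod2 P- replicates 1 (0.0882) or 3 (0.0801).

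Lists that did not pass in P- were phosphate transport (3 higher and 1 lower, camera adjusted p = 0.094), salicylate (4 and 0, 0.067), photorespiration (0 and 0, 0.701), starch and sugar (3 and 2, 0.306) and plastid-encoded genes (0 and 0, 0.19). Iron genes (3 and 3, camera adjusted p = 0.359) had a median of -0.10, a mean of 0.12 and a camera direction downward, and mitochondrion-encoded genes (0 and 0, 0.952) a median of 0.02 and a direction downward. Without phod2 P- replicate 2, 3 iron genes were higher and 5 lower with a median of -0.019, and the median of mitochondrion-encoded genes was -0.07. Phosphate transport (camera adjusted p = 0.0278) and plastid-encoded genes (0.0189) passed with the length trend removed. Salicylate genes passed without KC P+ replicates 1 (0.0356), 2 (0.0376) or 3 (0.0378), KC P- replicates 1 (0.0267), 2 (0.0482) or 3 (0.0486) or phod2 P+ replicates 2 (0.0371) or 3 (0.0391). Clock genes were called in 2 of 28 cases, PRR5 (-1.32 ± 0.261) and ELF4 (-1.49 ± 0.168), both lower in phod2. Anthocyanin synthesis held 7 higher genes of 18 (0.386 expected, one-sided hypergeometric adjusted p = 2.56e-05), phosphate starvation 11 of 62 (1.33 expected, adjusted p = 2.56e-05) and, among lower genes, hydrogen peroxide catabolism 15 of 83 (2.16 expected, adjusted p = 1.12e-06), of 8 and 14 terms past the threshold. Of the genes called in P+ and in P-, 571 were shared, with 192 higher in both (9.21 from independent lists), 374 lower in both (27.8) and 5 in opposite directions (35.4), at r = 0.606 across genes.

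The interaction asked which changes between P- and P+, whether with phosphate or time of day, differed between genotypes. Of the iron genes, IRT1 and FRO2 responded less in phod2, where neither was called, as IRT1 rose by a log2 of 3.98 ± 0.098 in KC and stood at 20.4 ± 1.2 (P+) and 25.3 ± 2.21 (P-) in phod2. FRO2 rose 16.6-fold in KC and stood at 16.4 ± 1.34 and 20.01 ± 4.49, and CYP82C4 rose 57.8-fold in KC and fell 2.17-fold in phod2. BHLH101 fell in both genotypes (-1.16 ± 0.426 in KC and -2.68 ± 0.418 in phod2), and its interaction was not called. SPX1, PAP17, PS2, VPE1 and GDPD1 also rose by a smaller factor in phod2 than in KC. The flavonoid genes CHS, F3PH and FLS1 responded more in phod2, as CHS rose by a log2 of 4.19 ± 0.105 there and 1.82 ± 0.094 in KC, F3PH 28.5-fold and 5.67-fold, and FLS1 11.4-fold and 4.21-fold. CRU1 rose 5.69-fold in phod2 and fell 2.71-fold in KC. ASN1, an asparagine synthetase gene of carbon starvation, fell 12.9-fold in phod2, and its log2 change in KC was -0.70 ± 0.064.

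The interaction was called for 643 genes, 500 with a more positive and 143 with a more negative change in phod2. Of these, 126 were called between conditions in KC only, 222 in phod2 only, 176 in both in the same direction, 17 in both in opposite directions and 102 in neither. For IRT1 the interaction was -3.67 ± 0.128 and for CHS 2.36 ± 0.132, with adjusted p of 9.65e-10 and 1.14e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 3 libraries in each of the 4 groups. The library with the length trend belongs to this contrast, and without it 772 genes were called. On the log2(FPKM + 1) scale limma called 355.

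Flavonoid genes had 9 of 23 members with a more positive change in phod2 (camera adjusted p = 2.13e-15), seed markers 6 of 9 (7e-06), root hair markers 2 of 11 (0.00112) and heat shock genes 1 of 15 (3 adjusted over the list alone, 7e-06). After quantile normalization root hair markers missed the camera threshold (adjusted p = 0.219). Their called members RSL2 and PRX44 were then under 2-fold (0.53 and 0.84), as they were on log2(FPKM + 1) (0.57 and 0.90). Iron genes had 5 of 26 members with a more negative change and 0 with a more positive (camera adjusted p = 1.21e-09). Jasmonate genes had 4 more positive (6 adjusted over the list alone) and 1 more negative (camera adjusted p = 0.000192), and root tissue markers 3 and 1 (0.000955). Phosphatases had 4 and 2 (camera adjusted p = 0.0488, and adjusted p = 0.126 with an estimated correlation), nuclear photosynthesis genes 0 and 0 (0.0488, and adjusted p = 0.792 with an estimated correlation) and plastid-encoded genes 0 and 2 (7e-06, and adjusted p = 0.101 with an estimated correlation). Phosphatases missed the camera threshold with median ratio scaling (0.05 after rounding), with the length trend removed (0.0712) and without phod2 P- replicates 1 (0.0819) or 3 (0.0849). Photosynthesis missed it after quantile normalization (0.982), with the length trend removed (0.22) and without KC P+ replicates 2 (0.0723) or 3 (0.0636), KC P- replicates 1 (0.0528) or 2 (0.0836), phod2 P+ replicates 1 (0.065) or 3 (0.0814) or phod2 P- replicate 2 (0.487). Without the library that showed the length trend, the flavonoid, seed and iron numbers were 9, 6 and 6, while the plastid-encoded number was 7 and 3 heat shock genes were more positive. The photosynthesis median was 0.076 without it and 0.21 with it. The heat shock gene called with all libraries, HSP70 (1.01), was under 2-fold in 13 of the other settings, such as 0.91 on log2(FPKM + 1) and 0.98 without KC P+ replicate 1. The phosphate lists of transport (2 and 1, or 3 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 0.441), signalling (1 and 1, median -0.05, or -0.081 on log2(FPKM + 0.1), mean 0.01, downward, 0.85) and lipid remodelling (2 and 1, median 0.11, reversed to -0.031 on log2(FPKM + 0.1), 0.404) did not pass. Sulfate genes (1 and 2, median -0.04, mean 0.02, upward, camera adjusted p = 0.604), salicylate (3 and 2, median -0.12, mean 0.35, downward, 0.774), mitochondrial dysfunction genes (1 and 1, median -0.02, mean -0.03, upward, 0.85), glucosinolate (0 and 0, 0.0632), starch and sugar (0 and 2, 0.0809), lipoate (0 and 0, 0.224), plastid fatty acid synthesis (0 and 0, 0.339), photorespiration (0 and 0, 0.284, or 0.029 after quantile normalization and 0.0112 without phod2 P- replicate 2) and mitochondrion-encoded genes (0 and 0, 0.662) did not pass either. Without phod2 P- replicate 2 the medians were 0.24 for lipid remodelling, -0.007 for signalling, 0.052 for sulfate, 0.004 for salicylate and -0.07 for mitochondrial dysfunction genes, with 2 sulfate genes more positive and 0 mitochondrial dysfunction genes more negative. Of the clock genes 1 of 28, LNK1, was called. Flavonoid biosynthesis held 8 more positive genes of 21 (0.532 expected, one-sided hypergeometric adjusted p = 1.76e-05), and cellular response to iron ion 5 more negative genes of 27 (0.203 expected, adjusted p = 0.000984), of 9 and 5 terms past the threshold.

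**Figure D5:**
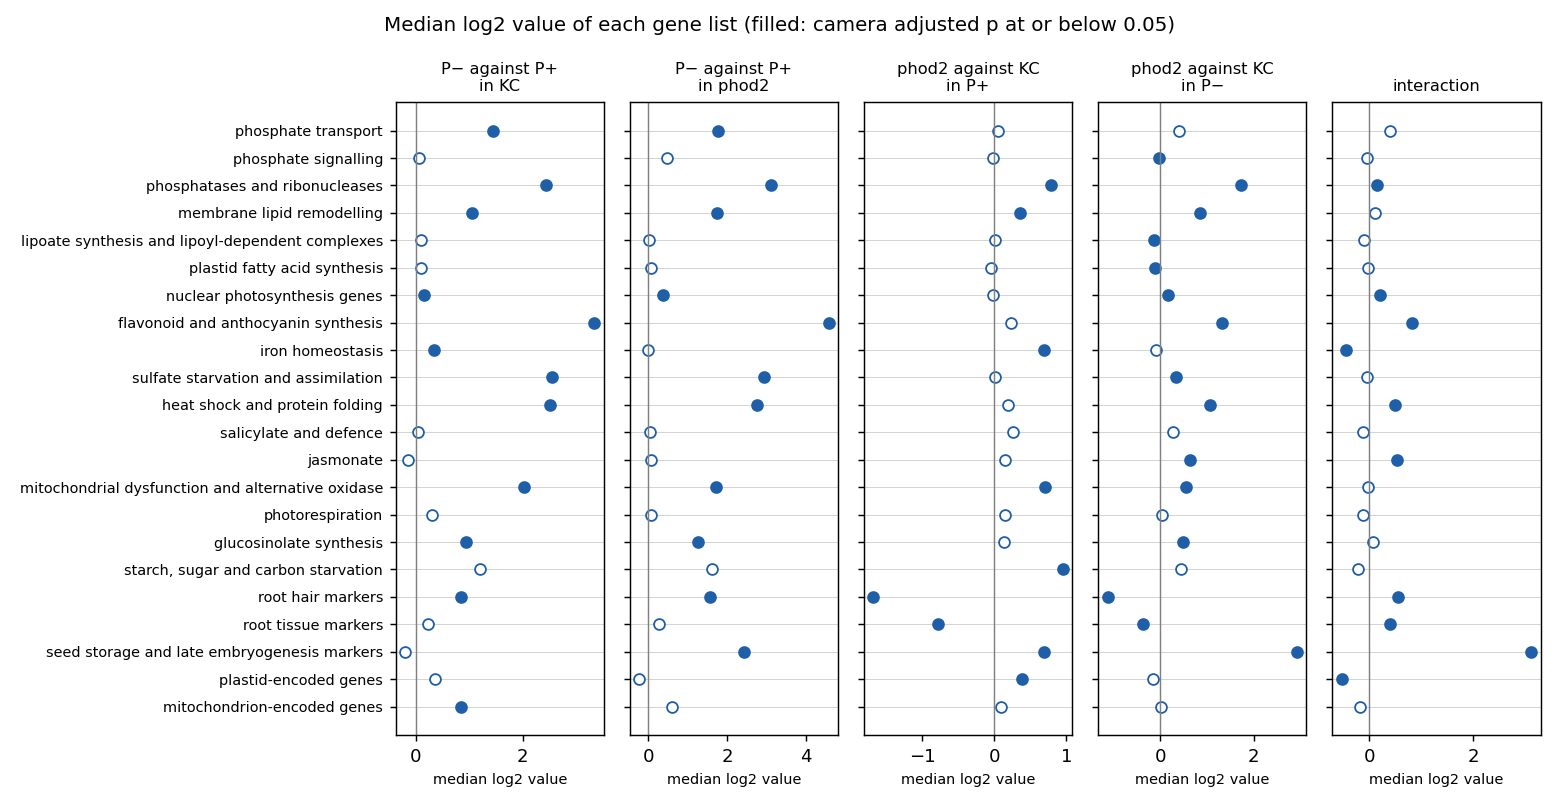
Median log2 fold change (horizontal axis) of each of the 22 gene lists (vertical axis) in the 5 contrasts, 1 panel each, with filled points for lists at a camera adjusted p of at most 0.05. Flavonoid genes lie at 3.35 and 4.57 for P- in KC and phod2 and at 0.82 in the interaction, and iron genes at -0.45 in the interaction.

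With an estimated correlation between genes, 7 of the 12 lists past the camera threshold kept their place for P- in KC, 9 of 11 for P- in phod2, 6 of 9 for phod2 in P+, 10 of 15 for phod2 in P- and 7 of 10 for the interaction.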

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

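The interaction, the fits with each library left out, the regroupings of libraries and the test of a length trend shared by phod2 in P- were planned before their results were seen. The other tests of explanations in this part, the use of a left-out library as such a test and the size of the larger draw of regroupings were chosen only after the result was seen.

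The test of the difference itself, the interaction of genotype and condition, set apart 643 genes, 10 lists and 48 named genes, 28 of them more positive in phod2 and 20 more negative. With an estimated correlation between genes 7 of the 10 lists passed, while phosphatases (camera adjusted p = 0.126), nuclear photosynthesis genes (0.792) and plastid-encoded genes (0.101) did not. List medians of the interaction were 3.11 for seed markers, 0.82 for flavonoid genes, 0.56 for root hair markers, 0.53 for jasmonate, 0.50 for heat shock, 0.41 for root tissue markers, 0.21 for nuclear photosynthesis genes, 0.15 for phosphatases (0.378 on log2(FPKM + 0.1)), -0.45 for iron genes and -0.53 for plastid-encoded genes. Without phod2 P- replicate 2 the photosynthesis median was 0.076 and its camera adjusted p 0.487, and after quantile normalization the camera adjusted p was 0.219 for root hair markers. When the genotype labels were exchanged among libraries within each condition, 60 of 200 possible regroupings were drawn first, of which 1, the real one, called as many genes (643, against 408 for the highest other). The draw was then enlarged to 100 that include these 60, and 5 of them, the real one included, called as many genes (1247 for the highest other). The share in the larger draw is not under 0.05, so chance is not excluded by it. The 4 others called 1018 to 1247 genes, and each kept the genotypes apart in P+ and exchanged 2 of the 3 libraries of each genotype in P-, an arrangement that by construction turns a genotype difference shared by both conditions into an interaction. The 91 regroupings that mixed the genotypes in P+ called at most 215 genes; this breakdown was looked at after the result.

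Log2 values more positive in phod2 were led by EIL4 (5.46), AIG2LA (5.17), CRU3 (4.75) and DTX20 (4.44), of which EIL4, CRU3 and DTX20 had 1 count and AIG2LA 2 counts in a whole group, so that these fitted values depend on the prior count. Seed genes followed with CRU1 at 3.95, PER1 at 3.18 and OLEO2 at 3.11. Defence and jasmonate genes included PR2 (3.09), WRKY18 (1.59), VSP1 (2.38), AOC1 (1.13) and AOC2 (1.07). Flavonoid genes included CHS (2.36), F3PH (2.33) and FLS1 (1.44). Phosphate and lipid genes included GDPD3 (2.19), PHT3;2 (2.01), PHT1;5 (1.95), PAP22 (1.75), WRKY75 (1.57) and NPC4 (1.22). The root genes TIP2;3, RSL2, PRX44 and ASFT stood at 1.65, 1.62, 1.27 and 1.23, and GGCT2;1, UGT74E2 and HSP70 at 2.34, 1.04 and 1.01. Some of these calls ended without a single library (adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). They were AIG2LA without KC P+ replicates 1 (0.0571) or 3 (0.204), KC P- replicates 1 (0.0541) or 2 (0.0543) or phod2 P+ replicates 2 (0.0632) or 3 (0.0664), CRU3 without KC P+ replicates 2 (0.0559) or 3 (0.135) or KC P- replicates 2 (0.0742) or 3 (0.068), and PHT3;2 without KC P+ replicates 1 (0.112) or 2 (0.0688), KC P- replicates 1 (0.054) or 3 (0.0546) or phod2 P+ replicate 1 (0.0648). HSP70 and UGT74E2 came under 2-fold without some libraries, listed below (log2 0.903 to 0.997). After quantile normalization HSP70 (0.87), UGT74E2 (0.79), PHT3;2 (0.77), RSL2 (0.53), PRX44 (0.84), NPC4 (0.90), AOC1 (0.99) and AOC2 (0.85) were under 2-fold as well.

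Log2 values more negative in phod2 were led by CYP82C4 (-6.97), PDF1.2C (-4.42), GRXC11 (-4.07, with 1 count in phod2 P-) and FRO2 (-3.76). Iron genes also included IRT1 (-3.67) and NAS2 (-2.29), and starch and sugar genes ASN1 (-3.00) and SEN1 (-1.42). Phosphate genes included VPE1 (-2.43), PAP17 (-1.90), PS2 (-1.71), GDPD1 (-1.37) and SPX1 (-1.20). The sulfate transporter genes SULTR1;3 and SULTR1;1 stood at -2.25 and -1.64, the nitrate transporter gene NRT2.1 at -1.85, WRKY70 at -1.41 and NDB4 at -1.30. After quantile normalization SULTR1;3, NDB4 and GRXC11 turned positive (0.44, 0.63 and 0.072), as they did in 4, 5 and 3 further limma settings, and SULTR1;1 (-0.74) and PS2 (-0.83) were under 2-fold. NDB4 was not called in DESeq2 (adjusted p = 0.107). Nor was it in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without a filter (0.0529), under the replicate block (0.0632), or without the single libraries listed below (0.0567 to 0.141). The plastid-encoded genes TRNS.2 and PETD stood at -1.84 and -1.25.

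Morning-phased and evening-phased clock genes lay far apart between P- and P+ in both genotypes, and as they were listed after their values had been seen, their separation is no test of whether the pattern holds. Clock genes that follow the phosphate-starvation genes at the size seen for phod2 against KC in P+ were argued against. There 11 morning-phased and 10 evening-phased genes were separated by -0.106 ± 0.272 (log2, bootstrap SE over genes, which are not independent replicates). SPX1, IPS1, PAP17 and PHT1;4 rose less there than for P- in KC (SPX1 3.09 against 4.41), and MGD3 rose more. Clock genes that follow only a fuller starvation response therefore stay open. A harvest of P+ and P- seedlings at different times of day may account for the pattern, but the separation over 1 that it needs (7.61 ± 1.24 in KC) was measured on genes listed with the pattern known and does not decide for it. Phosphate supply acting on the clock itself needs the same, with 7.81 ± 1.34 in phod2, and cannot be told apart from harvest time because condition and any difference in harvest coincide in these libraries and the labels give no hour. The share of other called genes, also in the interaction, that goes with time of day was not tested.

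Replicate 2 of phod2 P- differed from its group by gene length, with a chi-square per gene of 30.6 and 32.0 against the other 2 libraries, compared with 1.39 to 2.17 for other replicate pairs. A length trend as the whole cause of the calls between phod2 and KC in P- was argued against, because 1025 genes were called without that library and 979 with it. A length trend shared by phod2 in P- was also argued against, as the Spearman correlation of log2 fold change with length went from -0.33 to -0.038 without it. For P- against P+ the same correlation was -0.138 in KC, and in phod2 it went from -0.267 to -0.159 without that library. That library thus does not account for the whole length trend between conditions, whose origin was not tested. An exchange with a library of another group was argued against, because its mean correlation was higher with its own group than with any other by 0.0191. A difference in RNA quality or library preparation of this library may account for its own trend, stays open and was not tested, and no biological explanation was tested.

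Root hair and root tissue markers were lower in phod2 than in KC in P+, where the KC columns are those headed WT. A smaller share of root tissue as the whole cause needs all markers to fall alike. They did not, since the SD of log2 fold change over 27 markers was 1.04 against a median SE of 0.125. Root tissue markers also had an SD of 0.83 for P- in KC, 0.77 for P- in phod2 and 0.45 for phod2 in P-. As these markers varied in every comparison, the spread cannot decide on a smaller root share. A larger fall of root hair markers than of other root markers may be part of the pattern, with means of -1.69 over 11 genes and -0.78 over 16. The 2-sided permutation p was 0.0218, from exchanging genes, which are not independent replicates. It does not measure the spread between libraries, so it does not decide for a larger fall. A smaller root share together with changes of single genes stays open, as does a genotype effect on root hairs, which the design names only through phod2.

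For the called genes of the 4 pairwise comparisons, 1 of 10 splits, the real one, gave as many genes in edgeR, at 4292 for P- in KC, 5102 for P- in phod2, 1545 for phod2 in P+ and 979 for phod2 in P-. The highest of the other splits gave 0 in each case, and 10 splits are too few for a share under 0.05.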

How the results depend on the processing

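Removal of a length trend per library, the fits of lists without phod2 P- replicate 2 and the filter at 10 normalized CPM were chosen only after the result was seen. Over 27 other settings, 167 named-gene results gave 4302 values, of which 4187 kept direction and side of the threshold, 100 lost the threshold, 0 gained it in any of these tools (edgeR, limma or DESeq2) and 15 reversed. Most of these results had been named because they were called in the same libraries, so most were likely to keep the call. Only LIP1P in the 4 pairwise comparisons and PHT1;4 in phod2 in P- were uncalled and could gain it. Counts of called genes stayed within 1.5 times in all 5 contrasts with a pseudocount of 0.1, no filter, DESeq2 and median ratio scaling, with length removal, and in the pairwise contrasts with only the 6 libraries compared. Leaving out a library gave 4252 to 4404 genes for P- in KC, 4886 to 5370 for P- in phod2, 1471 to 1698 for phod2 in P+, 925 to 1025 for phod2 in P- and 538 to 772 for the interaction, sharing at least 94.4%, 89.3%, 88.0%, 86.1% and 77.8% of the main calls.

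Fewer genes were called on the log2(FPKM + 1) scale, which shrinks changes of low genes by construction, with 2750 for P- in KC, 633 for phod2 in P+, 438 for phod2 in P- and 355 for the interaction. A pseudocount of 0.5 gave 878 and 566 for phod2 in P+ and P-. TPM gave 810, 528 and 410 for phod2 in P+, phod2 in P- and the interaction. Quantile normalization gave 2746, 3288, 592, 450 and 345 for the 5 contrasts in order (P- in KC, P- in phod2, phod2 in P+, phod2 in P-, interaction), and library weights gave 2761, 3188, 635, 427 and 363. Without a variance trend 2747, 631, 438 and 354 genes were called in all but P- in phod2. A mean of at least 5 FPKM, which tests fewer genes, left 2317, 2767, 472, 282 and 281, and a mean of at least 10 normalized CPM left 2106, 2531, 394, 228 and 224. No fold threshold gave 13483, 14200, 5878, 4712 and 2501. Overlaps without the fold threshold were 11125 in the same and 214 in opposite directions for P- in both genotypes, 2289 and 243 for phod2 in both conditions, and 2510 and 1816 for P- in KC with phod2 in P+.

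In the interaction NDB4 (main -1.30) turned to 0.54 on log2(FPKM + 1) and without a variance trend, 0.41 at a pseudocount of 0.5, 0.40 on TPM, 0.63 after quantile normalization and 0.51 with library weights. SULTR1;3 (main -2.25) turned to 0.33 on log2(FPKM + 1) and without a variance trend, 0.024 on TPM, 0.44 after quantile normalization and 0.47 with library weights. GRXC11 (main -4.07) turned to 0.12 on log2(FPKM + 1) and without a variance trend, 0.072 after quantile normalization and 0.14 with library weights. Each had a low mean in one group (0.141 CPM for NDB4, 0.163 for SULTR1;3 and 0.0151 for GRXC11), and a pseudocount shrinks changes from such levels by construction. Some calls in the interaction ended without a single library (adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). For NDB4 these were KC P+ replicates 1 (0.141), 2 (0.0797) and 3 (0.134), KC P- replicates 1 (0.112) and 3 (0.0707), phod2 P+ replicates 1 (0.0938) and 3 (0.0601) and phod2 P- replicates 1 (0.0635) and 2 (0.0567). For AIG2LA they were KC P+ replicates 1 (0.0571) and 3 (0.204), KC P- replicates 1 (0.0541) and 2 (0.0543) and phod2 P+ replicates 2 (0.0632) and 3 (0.0664). For CRU3 they were KC P+ replicates 2 (0.0559) and 3 (0.135) and KC P- replicates 2 (0.0742) and 3 (0.068). For PHT3;2 they were KC P+ replicates 1 (0.112) and 2 (0.0688), KC P- replicates 1 (0.054) and 3 (0.0546) and phod2 P+ replicate 1 (0.0648). HSP70 came under 2-fold (log2) without KC P+ replicate 1 (0.981), KC P- replicate 3 (0.987), phod2 P+ replicate 2 (0.981) or phod2 P- replicate 1 (0.997) or 3 (0.991), and UGT74E2 without phod2 P+ replicate 1 (0.903) or phod2 P- replicate 3 (0.996). HSP70 also came under 2-fold without a filter (0.988), at pseudocounts of 0.1 (0.961), 0.5 (0.938) and 1 (0.911), on TPM (0.884), after quantile normalization (0.874), without a variance trend (0.911) and with library weights (0.983). UGT74E2 did so at pseudocounts of 0.1 (0.996), 0.5 (0.902) and 1 (0.811), on TPM (0.835), after quantile normalization (0.791), without a variance trend (0.811) and with library weights (0.877). On log2(FPKM + 1), a scale on which low genes shrink, further values under 2-fold were 0.70 for PHT3;2, 0.57 for RSL2, 0.90 for PRX44 and NPC4, -0.70 for SULTR1;1 and -0.72 for PS2 in the interaction, -0.67 for LBD14 in phod2 in P- and -0.86 for MYB12 in phod2 in P+. On TPM they were 0.86 for PHT3;2, 0.75 for RSL2, 0.97 for PRX44 and AOC2, 0.93 for NPC4, -0.91 for SULTR1;1 and -0.98 for LBD14, after quantile normalization 0.99 for AOC1, 0.85 for AOC2 and 0.98 for SQD1 in phod2 in P-, and with the length trend removed 0.975 for AOC2. NDB4 also missed the threshold in DESeq2 (adjusted p = 0.107) and without a filter (0.0529), and at a pseudocount of 0.1 it stood at -0.40 (adjusted p = 0.409 in limma).

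In camera, with an estimated correlation, adjusted p for P- in KC was 0.148 for membrane lipids, 0.678 for nuclear photosynthesis, 0.0898 for iron, 0.0811 for heat shock and 0.326 for mitochondrion-encoded genes; for P- in phod2 0.122 for membrane lipids and 0.748 for photosynthesis; for phod2 in P+ 0.0575 for membrane lipids, 0.123 for seed markers and 0.185 for plastid-encoded genes; for phod2 in P- 0.0753 for phosphate signalling and lipoate, 0.0722 for plastid fatty acid synthesis, 0.661 for photosynthesis and 0.11 for sulfate; and for the interaction 0.126 for phosphatases, 0.792 for photosynthesis and 0.101 for plastid-encoded genes. After quantile normalization it was 0.434 for photosynthesis, 0.0995 for iron, 0.818 for seed markers and 0.146 for mitochondrion-encoded genes in P- in KC, and 0.664 for lipoate, 0.63 for photosynthesis and 0.34 for photorespiration in P- in phod2. It was then 0.91 for flavonoid, 0.823 for heat shock and 0.102 for seed markers in phod2 in P+, 0.76 for photosynthesis (direction reversed) and 0.353 for photorespiration in phod2 in P-, and 0.773 for phosphate signalling, 0.982 for photosynthesis, 0.029 for photorespiration (gained) and 0.219 for root hair markers in the interaction.

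With the length trend removed, camera adjusted p was 0.11 for photosynthesis, 0.109 for iron, 0.85 for seed markers and 0.17 for mitochondrion-encoded genes in P- in KC, 0.0431 for phosphate signalling (gained), 0.879 for fatty acid synthesis and iron and 0.972 for salicylate in P- in phod2, and 0.0508 for seed markers and plastid-encoded genes in phod2 in P+. It was 0.0278 for phosphate transport and 0.0189 for plastid-encoded genes (both gained) and 0.155 for photosynthesis in phod2 in P-, and 0.79 for phosphate signalling, 0.0712 for phosphatases, 0.22 for photosynthesis and 0.928 for mitochondrial dysfunction in the interaction. On log2(FPKM + 0.1) it was 0.982 for seed markers and 0.0583 for mitochondrion-encoded genes in P- in KC, 0.91 for lipoate in P- in phod2, 0.149 for seed markers and 0.975 for mitochondrion-encoded genes in phod2 in P+, and 0.0509 for phosphate signalling in phod2 in P-. With median ratio scaling it was 0.05 for phosphatases in the interaction. On log2(FPKM + 0.1) the median log2 change was 1.15 and 1.64 for phosphate transport in KC and phod2, 1.67 for phosphatases in KC, and 1.25, 1.60 and -0.031 for membrane lipids in KC, phod2 and the interaction. Within the SD of library medians but over 1.5 times apart were phosphatases in the interaction (0.15 in edgeR and 0.378 on that scale) and phosphate signalling in KC (0.059 and 0.031) and in the interaction (-0.045 and -0.081). The cause was not tested for any list.

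Without a single library, camera adjusted p ran from 0.0253 to 0.113 for iron, 0.876 to 0.997 for seed markers and 0.0249 to 0.101 for mitochondrion-encoded genes in P- in KC. Iron lost the threshold without KC P+ replicate 2 (0.0622), phod2 P+ replicates 2 (0.0524) and 3 (0.0521) and phod2 P- replicates 1 (0.0544), 2 (0.113) and 3 (0.0523). Mitochondrion-encoded genes lost it without KC P+ replicates 1 (0.0597) and 2 (0.0661), KC P- replicates 1 (0.0596) and 2 (0.0532) and phod2 P- replicates 1 (0.0544), 2 (0.101) and 3 (0.0549). In P- in phod2 the ranges were 0.822 to 0.971 for iron, 0.891 to 0.984 for salicylate and 0.04 (gained without phod2 P+ replicate 2) to 0.258 for mitochondrion-encoded genes. In phod2 in P+ fatty acid synthesis (0.0351 to 0.24) and photorespiration (0.0111 to 0.175) gained at their lowest values, without phod2 P- replicate 2, and mitochondrion-encoded genes ran from 0.203 to 0.88.

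In phod2 in P- phosphate signalling (0.0315 to 0.0726) lost the threshold in camera without KC P- replicate 3 (0.0536) and phod2 P- replicates 1 (0.0642) and 3 (0.0726). Photosynthesis (9.03e-05 to 0.721) reversed without phod2 P- replicate 2 (0.721), and sulfate (0.0204 to 0.0882) lost it without phod2 P- replicates 1 (0.0882) and 3 (0.0801). Salicylate (0.0267 to 0.114) gained it without KC P+ replicates 1 (0.0356), 2 (0.0376) and 3 (0.0378), KC P- replicates 1 (0.0267), 2 (0.0482) and 3 (0.0486) and phod2 P+ replicates 2 (0.0371) and 3 (0.0391). Photorespiration ran from 0.439 to 0.792 and mitochondrion-encoded genes from 0.628 to 0.994. In the interaction phosphatases (0.00195 to 0.0849) lost it without phod2 P- replicates 1 (0.0819) and 3 (0.0849). Photosynthesis (0.00145 to 0.487) lost it without KC P+ replicates 2 (0.0723) and 3 (0.0636), KC P- replicates 1 (0.0528) and 2 (0.0836), phod2 P+ replicates 1 (0.065) and 3 (0.0814) and phod2 P- replicate 2 (0.487). Photorespiration (0.0112 to 0.573) gained it without phod2 P- replicate 2 (0.0112). Phosphate signalling ran from 0.748 to 0.965, salicylate from 0.8 to 0.999 and mitochondrial dysfunction from 0.652 to 0.977. The cause was not tested.

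The replicate numbers did not pair the samples, since the 18 pairs of equal number had correlations of -0.063 to 0.062 and 4 of 12 libraries correlated best with their own number. With a replicate block 4287, 5104, 1529, 967 and 617 genes were called. Under the block, camera adjusted p was 0.0529 for iron and mitochondrion-encoded genes in P- in KC and for phosphate signalling in phod2 in P-, and 0.0463 for salicylate in phod2 in P- (gained). NDB4 missed the threshold under the block (adjusted p = 0.0632), and no other named gene did.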

Other observations

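Every gene in this part was chosen only after its values were seen, and no explanation was tested. Genes of the marneral cluster on chromosome 5 (17023502 to 17058245), which make a root triterpene, were lower in phod2. In P+, MRN1 fell by 6.51 ± 0.28 on the log2 scale (SE, n = 3 per group), CYP705A12 by 4.03 ± 0.224 and MRO by 3.10 ± 0.137. In P- the falls were smaller, with MRN1 at -4.02 ± 0.198, CYP705A12 at -1.84 ± 0.17 and MRO at -1.56 ± 0.115. Genes of the thalianol cluster farther along the chromosome (19428888 to 19461706) were also lower in phod2, as THAA1, THAO, THAS1 and THAH stood at -3.26 ± 0.186, -2.78 ± 0.069, -2.73 ± 0.087 and -2.40 ± 0.07 in P+. In P- these 4 stood at -2.24 ± 0.18, -1.61 ± 0.068, -1.36 ± 0.09 and -0.89 ± 0.074, the last under 2-fold. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran for these 7 genes from 8.77e-12 for THAO to 1.32e-08 for THAA1 in P+. The interaction was called for all 7, from 1.02 ± 0.284 for THAA1 to 2.49 ± 0.513 for MRN1. For P- against P+, however, the clusters differed. MRN1, CYP705A12 and MRO rose within phod2 (2.78, 2.29 and 1.81) and were not called in KC. THAS1 and THAH fell within KC (-1.82 and -1.81), THAO and THAA1 were not called there, and none of these 4 was called in phod2. The KC P+ libraries behind the P+ values are those headed WT.

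Of 5 genes with roles in light responses, ELIP1, ELIP2 and PIF5 were called between conditions in both genotypes. ELIP1, an early light-induced protein gene, was higher in P- by 6.22 ± 0.142 in KC and 6.85 ± 0.135 in phod2, and ELIP2 by 7.41 ± 0.192 and 8.65 ± 0.208. PIF5, a phytochrome-interacting factor gene, was higher by 2.57 ± 0.077 and 2.67 ± 0.078, while PIF4 differed by 0.20 ± 0.057 and 0.09 ± 0.058 and was not called. HY5, a light-signalling factor gene, differed by 0.62 ± 0.126 in KC, under 2-fold, and was called in phod2 at 1.57 ± 0.134.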
